A study of Mus musculus with 10 samples.

How the data were processed

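Lung tissue of 10 BALB/c mice, 5 control and 5 challenged with intranasal IL-33, was taken into RNA preservative, and RNA was extracted with a spin column kit, per the labels. PolyA-selected RNA was made into libraries with a kit that keeps strand, per the labels. The submitters' processing notes name FastQC 0.11.6 and MultiQC 1.6 for read quality, STAR 2.5.4b for alignment, HTSeq 0.9.1 for counting and the GRCm38 genome. The annotation release, the strand setting of the counting and the read length are not given in the sources used here, so counts of overlapping or antisense genes could hold reads of their neighbours. The deposited files give raw counts of reads per gene for each library, with no normalization. They list 53465 genes, of which 53274 matched a symbol by identifier.

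Entries that name no gene were left out of library sizes and tests. Of all records they held 10.4% to 13.7% in no gene, 0.862% to 0.945% ambiguous and 15.0% to 22.8% multiply aligned. Unaligned reads are not counted in the files. Counted reads came to 7805175 to 13767118 per library, and 3 reads, the floor used for a count of 0, stand for 0.218 to 0.384 CPM in 1 library. Counts of 2 libraries of a group differed far beyond sampling noise for every pair (chi-square per degree of freedom 5.09 to 27.6), so none was treated as a duplicate.

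Groups were taken from the treatment label. All 10 libraries entered 1 fit in edgeR 4.0.16 (R 4.3.3) with group as the only term, TMM factors (0.969 to 1.03), the filterByExpr filter and the quasi-likelihood test, with Benjamini-Hochberg adjusted p at 0.05. The biological coefficient of variation was 0.136. The SE of a log2 fold change comes from log2(CPM + 0.1) over the 5 and 5 libraries, while the change itself comes from the edgeR fit. The 35 gene lists were fixed before the data were examined, and 34 with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Il36rn of the IL-1 family list matched no identifier. Library measures were compared with two-sided exact permutation tests, adjusted over 5 measures.

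The named genes followed a rule fixed before the data were examined. It takes the 12 largest rises and 12 largest falls among genes past the adjusted p with a mean of at least 1 CPM and no overlap between groups, leaving out antigen receptor segments, numbered gene models and pseudogenes. It adds, of each list, the 2 called members with the largest change at 1 CPM or more and the most abundant member, and Il33 and Il1rl1 in any case. This gave 108 genes, of which 1 is not reported here. Members of lists, gene families and single genes printed outside the rule were chosen after their values were seen. With 1 to 3 control counts the ratio of summed counts is given with an exact 95% binomial interval, and with 0 a bound against 3 counts over the group.

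Alternatives fixed beforehand were DESeq2 size factors or library size alone in edgeR, no low-count filter, at least 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, 1 surrogate variable from sva 3.50.0, scaling without the 50 most abundant genes, a test against a 1.5-fold change, an adjusted p of 0.01 and leaving out each library. A correction that removes each library's trend on exonic length and GC content through offsets was added after the data were seen. Shared sequence was measured as the percent of a gene's 75-base windows found in another gene, with 50 and 100 bases beside it. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the library measures and plots.

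The fit was tested on counts simulated for this comparison over 15037 genes, 200 of them changed. It recovered 53.7% of 1.5-fold, 85.1% of 2-fold and 95.5% of 4-fold changes, and 2.5% of calls were false. With a length trend of 0.3 log2 units per doubling added, 4314 genes were called before and 163 after the length and GC correction, and 79% of changed genes were recovered. That trend rose with length, opposite in sign to the one in the data, and was unrelated to the changed genes. Far more genes passed in the data than were changed here. The adjusted cutoff was therefore stricter here, and the shares recovered do not carry over.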

Results

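The series holds lung RNA of 10 BALB/c mice, 5 described as untreated controls and 5 given the cytokine IL-33, an epithelial alarmin, through the nose. The challenged mice received 1 µg in 35 µL on each of 5 days, and lungs were taken 24 hours after the last dose. Control libraries held 8935159 to 13767118 reads counted in genes and IL-33 libraries 7805175 to 13178798. Whether controls received vehicle is not given in the sources used here, so an effect of the instillation itself is not separated from that of IL-33. The comparison asks how repeated airway IL-33 changed the lung transcriptome. Levels below are reads scaled to library size (CPM), as mean ± SD of 5 libraries per group, and log2 fold changes are IL-33 over control. Rises and falls "by" a value, and values with no unit beside a gene, are on that log2 scale.

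Chil4, a chitinase-like protein of activated macrophages and epithelium (chromosome 3, 106201490 to 106219507), rose from 0.966 ± 0.364 to 1421 ± 680.4 CPM, a log2 fold change of 10.53 ± 0.45 (SE). Retnla, a resistin-like protein of alternatively activated macrophages (chromosome 16, 48842551 to 48844461), rose from 76.0 ± 47.1 to 16098 ± 2105 CPM. Among falls, Pon1, a paraoxonase, went from 37.5 ± 6.76 to 1.81 ± 0.836 CPM and Scgb3a2, a club cell secretoglobin (chromosome 18, 43764289 to 43767399), from 419 ± 106 to 51.1 ± 20.8 CPM. Il33 itself, ENSMUSG00000024810 at chromosome 19, 29925114 to 29960718, rose from 90.2 ± 14 to 332 ± 31 CPM, and its receptor gene Il1rl1, ENSMUSG00000026069 at chromosome 1, 40429570 to 40465415, from 7.11 ± 0.868 to 216 ± 35.0 CPM. Positions span each whole gene, from first to last exon, in the GRCm38 annotation.

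The 12 largest rises that met the naming rule also included Rnase2a, an eosinophil-type ribonuclease (log2 9.32 ± 0.64), Retnlb, a goblet cell resistin-like protein (log2 8.37 ± 0.24), Arg1, the arginase of alternatively activated macrophages (log2 8.12 ± 0.22), and Fxyd4, an ion transport regulator (log2 7.43 ± 0.59). Where controls held 1 to 3 reads in all, the ratio of summed counts was 715 (95% interval 244 to 3468) for Sprr2a3, 824 (95% interval 147 to 32578) for Tff1, 567 (95% interval 194 to 2750.4) for Il13, 353 (95% interval 63 to 14002) for Epx and 303 (95% interval 54.0 to 12019) for Msx3. Of Sprr2a3's 75-base windows 51.1% occur in another gene, so its level is uncertain. Klk4 had 0 control reads and was at least 50.5-fold higher against a floor of 3 counts over the group. Retnlb had 5 control reads in all, a mean of 0.087 CPM, below the 0.1 CPM added for the SE. Its SE of 0.24 may therefore be too small. Intervals and floors cover counting error only. Single control libraries set several of these values. Without control 2, Rnase2a stood at 9.98, Fxyd4 at 8.75, the Sprr2a3 ratio at 1782, and Tff1 at least 228-fold higher with 0 control reads left. Without control 1 the Il13 ratio was 1256 and Msx3 was at least 74.7-fold higher, and without control 4 Epx was at least 93.0-fold higher. The largest falls included Vstm2a (log2 -4.68), Pon1 (-4.31), Galnt13 (-3.61), Esm1, an endothelial tip cell gene (-3.56), Wnt10b (-3.53), Glb1l3 (-3.24), Myl3, a cardiac and slow muscle myosin light chain (-3.22), Scgb3a2 (-3.03), Gria1 (-2.93), Abca17 (-2.83) and Abi3bp (-2.81). These rises and falls had adjusted p of 4.58e-06 or less by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The naming rule took only genes with no overlap between groups.

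Of 15695 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 10975 (69.9%) passed an adjusted p of 0.05. Of these, 5508 were higher and 5467 lower in IL-33 lungs. At least 2-fold, 2278 rose and 1379 fell, and at least 4-fold 841 rose and 116 fell. With no low-count filter, 3422 rose at least 2-fold. Of the tested genes, 8862 (56.5%) had no overlap between the 5 control and 5 IL-33 values, where chance gives 0.794%. The first principal component held 81.5% of the variance and separated the groups. Libraries correlated at 0.980 to 0.989 within controls, 0.975 to 0.989 within IL-33 and 0.851 to 0.924 between groups. The p-values set the difference between the groups against the spread between libraries within them. Counts moved over 1.5 times when the test asked for more than a 1.5-fold change, which left 4741 genes. After a correction for exonic length and GC content chosen after the data were seen, 10712 genes passed, of which 9048 kept their call and direction and 48 turned direction.

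**Figure D1:**
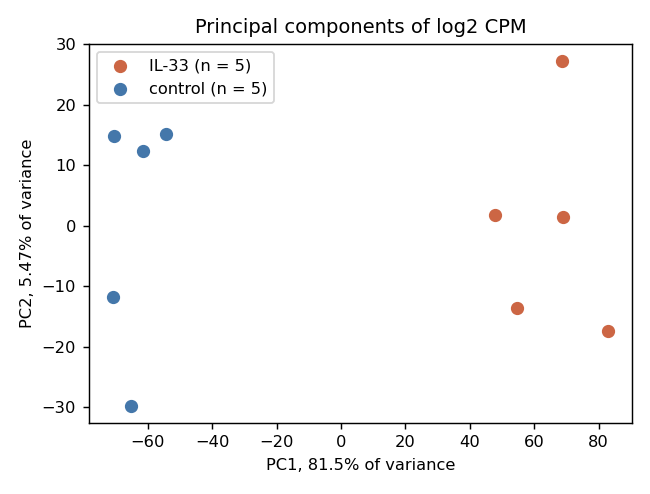
Principal components of log2 CPM, PC1 (81.5% of variance) against PC2 (5.47%), unitless scores, with 1 point per library (5 control, 5 IL-33). The groups lie on opposite sides of PC1.

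Shorter transcripts were higher in IL-33 libraries across the genome. With genes ordered by exonic length into 10 bins of equal size, the shortest bin, 48 to 1527 bases, had a median log2 fold change of 0.72, and the longest, from 9592 bases, had -0.31. Across 15685 genes, which are not independent replicates, Spearman's rho of log2 fold change with length was -0.33, and 0.02 with GC content. Ribosomal protein genes, which are short, rose in 76 of 78 cases, with a median of 1.48. That set was redefined after its values were seen: all symbols of Rpl or Rps and a digit gave 89 genes and a median of 1.31. Those 89 include S6 kinase genes, which are not ribosomal proteins, and leave out Rplp and Rpsa genes. The 4 genes called lower among them, Rps6kb1, Rps6ka2, Rps6ka6 and Rps6kc1, are such kinase genes. The length and GC correction moved Scgb1a1 from -0.51 to -1.47, Ear2 from 2.44 to 1.62 and Retnla from 7.73 to 6.83 (log2). It moved Rnase2a from 9.32 to 8.503, Retnlb from 8.37 to 7.59, Ear6 from 7.36 to 6.73, Itln1 from 6.89 to 6.30, Ccl8 from 6.44 to 5.49 and Ly6g from 5.30 to 4.69. Camp went from 5.20 to 4.47, Timp1 from 4.61 to 3.88, Scgb3a2 from -3.03 to -3.75, Fabp1 from -2.78 to -3.68 and Ppbp from -1.38 to -1.99. All of these passed both times. The correction also gave Sftpc, which did not pass at -0.05, a passing value of -0.67.

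**Figure D2:**
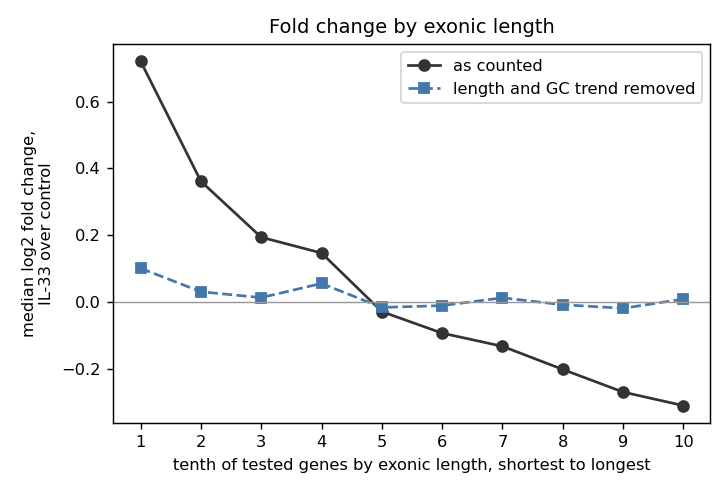
Median log2 fold change (IL-33 over control) of the tested genes in 10 bins of exonic length, from shortest to longest. Circles are values as counted, from 0.72 to -0.31, and squares are values after each library's trend on length and GC was removed.

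Genes of the IL-33 receptor and of group 2 innate lymphoid cells, tissue lymphocytes that respond to IL-33, rose in 19 of 21 cases and fell in 2. Il17rb had a log2 fold change of 6.6, Il5 6.40, Klrg1 5.14 and Gata3 3.64, while Il1rap fell by 1.05 and Il18r1 by 0.82. The set test limma camera gave an adjusted p of 4.01e-21, and 0.00540 with an estimated correlation. Of 18 type 2 cytokines, receptors and alarmins, 12 rose and 4 fell (camera adjusted p = 0.000453, adjusted p = 0.0858 with an estimated correlation). Il13ra2, the decoy IL-13 receptor, had 2 control reads and a ratio of 175 (95% interval 48.0 to 1448), which became 292 without control 3 and 281 without control 5. Il4 rose by 4.07. List members printed here and below that are neither among the 2 called members with the largest change nor the most abundant of their list were chosen after their values were seen. For each of the 34 tested lists except the ciliated cell genes, the counts adjusted over the list alone equalled those over all genes.

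Eosinophil genes rose in 12 of 15 cases, with Epx named above, Ear6 at log2 7.36 and the granule protein gene Prg2 at 6.92. Prg3, another granule protein gene, had 0 control reads and was at least 29.0-fold higher against a floor of 3 counts over the group. Ear2, which is also in the resident alveolar macrophage list, went from 48.4 ± 6.91 to 263 ± 33.2 CPM. Which cells held it was not tested. Of Ear2's 75-base windows 21.7% occur in another gene, so its level is uncertain. Siglecf, shared by eosinophils and alveolar macrophages, fell by 0.56. The camera adjusted p was 4.71e-12, and 0.0380 with an estimated correlation. Of 20 alternative macrophage activation genes, 18 rose, including Arg1, from 1.6 ± 0.447 to 441 ± 88.8 CPM, Pdcd1lg2 (log2 5.57) and Ccl17 (4.79), while Flt1 and Tgm2 fell (camera adjusted p = 2.74e-19, 0.00540 with an estimated correlation). All 6 tested chitinase family genes rose. Chia1, acidic chitinase, went from 87.9 ± 9.27 to 1902 ± 270.2 CPM and Chil3 from 180.5 ± 75.9 to 3599 ± 354 CPM; Chil3 shares 16.9% and Chil4 11.2% of windows with other genes (camera adjusted p = 1.28e-07, 0.00540 with an estimated correlation).

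Resident alveolar macrophage genes moved both ways, 6 higher and 7 lower of 17. Fabp1 fell by 2.78 and Marco, a scavenger receptor, by 1.14, while Chil3, Ear2 and Ctsk rose. The list's median was -0.05 and its mean 0.19, on opposite sides of 0, and camera, which put it higher, did not call it (adjusted p = 0.564). Of 20 monocyte and recruited macrophage genes, 13 rose, with Mmp12, macrophage elastase, going from 15.9 ± 5.73 to 456 ± 115 CPM and Spp1, osteopontin, from 43.9 ± 3.74 to 537 ± 208 CPM. Ace fell from 2046 ± 218 to 804 ± 117 CPM, and Ly6c2 had 0.03. Camera gave an adjusted p of 9.45e-06 (adjusted p = 0.0767 with an estimated correlation).

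Chemokine genes rose in 21 of 25 cases and fell in 3. Ccl24, an eosinophil chemoattractant, went from 0.890 ± 0.302 to 90.3 ± 22.9 CPM, Ccl8 from 1.87 ± 0.928 to 161 ± 46.2 CPM and Ccl11 rose by 5.17, while Cx3cl1 fell by 1.87. The camera adjusted p was 1.45e-09 (adjusted p = 0.0858 with an estimated correlation). Of 17 complement genes, 10 rose, among them C3, from 791 ± 81.4 to 3949 ± 519 CPM, C1qb, from 21.5 ± 1.65 to 166 ± 33.4 CPM, and Cfi, log2 3.79 (camera adjusted p = 1.39e-06, 0.0204 with an estimated correlation). Eicosanoid pathway genes rose in 15 of 20 cases. Alox15, the arachidonate lipoxygenase, went from 2.65 ± 1.14 to 153 ± 10.8 CPM, Ltb4r1 rose by 3.89, and Hpgd, which inactivates prostaglandins, fell from 421 ± 99.3 to 184 ± 55.0 CPM. Ptgdr had 3 control reads and a ratio of 74.5 (95% interval 25.1 to 364). Camera gave 1.28e-08 as adjusted p, and 0.00859 with an estimated correlation.

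All 24 cell division genes rose. Mki67, a marker of cycling cells, went from 17.6 ± 2.21 to 222 ± 41.8 CPM, Birc5 had a log2 fold change of 4.69 ± 0.31 and Cdk1 3.86 ± 0.18, with a list median of 3.0 (camera adjusted p = 7.7e-35, 0.0494 with an estimated correlation). Mucous metaplasia genes, which mark goblet cells, rose in 18 of 19 cases. Muc5ac, a gel-forming mucin, rose by 5.17, Slc26a4 by 6.01 and Itln1 from 1.73 ± 0.239 to 204 ± 105 CPM. Clca1 had a log2 fold change of 6.46, but control 2 held 82.9 CPM against 0.965 to 14 in the other controls, and without it the value was 8.38. The list passed camera (adjusted p = 2.25e-07; adjusted p = 0.172 with an estimated correlation).

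T cell genes rose in 14 of 20 cases. Ctla4 went from 3.89 ± 1.23 to 115 ± 38.9 CPM, Ccr4 from 1.11 ± 0.207 to 19.8 ± 5.22 CPM, and Foxp3, of regulatory T cells, rose by 2.77, while Cd8a fell by 0.77 and Cd8b1 by 0.89 (camera adjusted p = 2.54e-05; adjusted p = 0.330 with an estimated correlation). B and plasma cell genes rose in 13 of 19 cases, with Jchain going from 12.5 ± 6.77 to 262 ± 151 CPM and Ighm, the IgM heavy chain gene, from 179 ± 84.8 to 2592 ± 1793 CPM. Camera's adjusted p was 0.0405 (adjusted p = 0.520 with an estimated correlation); it was 0.0520 without control 2, 0.0763 without IL-33 library 5 and 0.0571 with the length trend removed. Of 14 type 1, natural killer and cytotoxic genes, 2 rose, Il18rap (1.65) and Ccl5 (0.87), and 1 fell, Il12rb2 (-1.25), and camera did not call the list (adjusted p = 0.671). After the length and GC correction 1 of these genes was higher and 6 were lower, with a median of -0.71.

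Neutrophil genes rose in 12 of 14 cases, with Ly6g at log2 5.30 (6.49 without control 1), Camp at 5.20 and Lcn2 going from 124 ± 27.8 to 448 ± 131 CPM; Csf3r, the receptor for granulocyte colony-stimulating factor, had -0.01 (camera adjusted p = 3.8e-05; adjusted p = 0.211 with an estimated correlation). Dendritic cell genes rose in 12 of 16 cases, among them Ccl22, from 5.30 ± 1.97 to 154 ± 21.3 CPM, and Batf3, log2 3.84, while Clec9a fell by 0.65 (camera adjusted p = 1.48e-05; adjusted p = 0.0858 with an estimated correlation). MHC class II and costimulation genes rose in 12 of 14 cases, with Cd74 going from 912 ± 125 to 2446 ± 224 CPM and Cd80 log2 2.42 (camera adjusted p = 1.7e-09; adjusted p = 0.0858 with an estimated correlation). Of 9 mast cell and basophil genes, 5 rose, Tpsab1 by 2.95 among them, and Kit and Gata2 fell. The list did not pass camera (adjusted p = 0.422). Kit stood at 310 CPM in controls against 0.459 for Tpsab1. Which lung cells held Kit and Gata2, or Ace and Flt1 of the macrophage lists, was not tested.

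**Figure D3:**
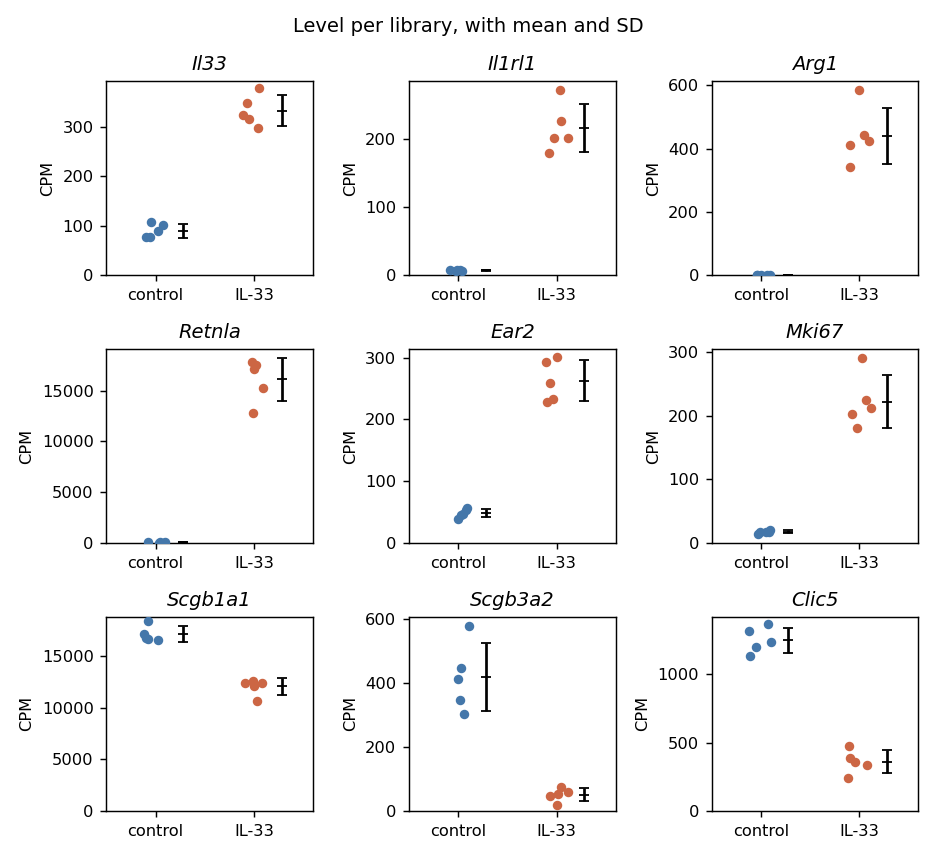
CPM per library (points) of 9 named genes, with mean and SD of 5 control and 5 IL-33 libraries; each axis starts at 0. Il33, Il1rl1, Arg1, Retnla, Ear2 and Mki67 lie higher, and Scgb1a1, Scgb3a2 and Clic5 lower, in all 5 IL-33 libraries.

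Alveolar type 1 cell genes, of the thin gas exchange epithelium, fell in 15 of 16 cases. Clic5 (chromosome 17, 44188584 to 44280172) went from 1247 ± 92.9 to 359.7 ± 84.9 CPM, Sema3e from 148 ± 11.5 to 42.6 ± 6.55 CPM and Ager from 1718 ± 149 to 1164 ± 78.6 CPM, while Pdpn had -0.05. The median was -1.20 (camera adjusted p = 1.45e-09; adjusted p = 0.0858 with an estimated correlation). Club cell genes fell in 12 of 15 cases. Scgb1a1, their main secretory product, went from 17128 ± 778 to 12069 ± 788 CPM, Cyp2f2 fell by 2.0, and Scgb3a1, Cldn10 and Lypd2 rose (camera adjusted p = 2.54e-05; adjusted p = 0.139 with an estimated correlation). Of 16 alveolar type 2 cell genes, 10 fell and 4 rose. Lyz1 went from 482 ± 27.2 to 79.6 ± 20.1 CPM, and Sftpd, a surfactant protein, rose by 1.11; camera did not call the list (adjusted p = 0.0650). It passed after the length correction (0.010), with no low-count filter (0.0106), without control 5 (0.0376) and without IL-33 library 4 (0.0284), each an adjusted p. Ciliated cell genes held 3 rises (2 adjusted over the list alone) and 6 falls of 16, with Mcidas at 1.33 and Hydin at -1.16 (camera adjusted p = 0.444).

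Endothelial cell genes fell in 14 of 23 cases and rose in 3. Calcrl went from 1605 ± 243 to 661 ± 154 CPM and Kdr fell by 1.55, while the venular adhesion gene Selp rose by 1.96 and Ackr1 by 2.63; Cldn5 had -0.01 and Vwf 0.28 (camera adjusted p = 0.00379; adjusted p = 0.234 with an estimated correlation). Extracellular matrix and remodelling genes rose in 13 of 24 cases, with Timp1, a metalloproteinase inhibitor, going from 4.74 ± 0.718 to 117 ± 44.9 CPM and Col3a1 up by 1.05, while Sparc, the most abundant, had -0.12 (camera adjusted p = 0.00379; adjusted p = 0.330 with an estimated correlation). Smooth muscle contractile genes held 4 rises and 7 falls of 15, with Chrm2 at -2.01, Casq2 at -1.53 and Mylk at -0.25, the last 0.07 and not called after the length correction (camera adjusted p = 0.602). Casq2 and Chrm2 are also expressed in heart, and 9 of 13 cardiac muscle genes fell, Myh6 from 649 ± 349 to 134 ± 66.6 CPM (camera adjusted p = 0.0370; adjusted p = 0.683 with an estimated correlation). Without control 2, control 5 or IL-33 library 5 that list's adjusted p was 0.0589, 0.0540 and 0.0712.

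Interferon-stimulated genes were mixed, 5 higher and 10 lower of 20, with Mx1 at log2 1.97 and Ifit2 at -1.68 (camera adjusted p = 0.340). IL-1 family and NF-kB pathway genes rose in 15 of 22 cases, with the decoy receptor Il1r2 at 4.75 and Il6 at 3.41, while Il18 fell by 1.91 (camera adjusted p = 0.00817, adjusted p = 0.328 with an estimated correlation). Nfkbia had 0.40 and was not called. It was called at 0.64 without control 1 and at 0.45 with the replicate block. It was 0.19 and not called without IL-33 library 1, and -0.016 after the length correction. Circadian clock genes fell in 11 of 16 cases and rose in 3. Nr1d1, a clock repressor, went from 384 ± 125 to 95.1 ± 31 CPM, Tef from 343 ± 105 to 145 ± 43.1 CPM, and Nfil3 rose by 2.0; camera did not call the list (adjusted p = 0.105). It passed without control 1 (0.0399), without IL-33 library 4 (0.0485) and with no low-count filter (0.0178), each an adjusted p. Cholesterol synthesis genes held 6 rises and 6 falls of 17, with Mvd at 1.24 and Srebf2 at -0.31, the latter -0.021 and not called after the length correction (camera adjusted p = 0.726). Of 16 immediate early and heat shock genes, Egr2 (1.51) and Junb (1.34) rose and 14 did not pass (camera adjusted p = 0.726). Jun, the most abundant, had -0.62 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0829). It passed as lower with no low-count filter (0.0223), the replicate block (0.00533), a surrogate variable (0.0472), the length correction (0.0494), limma-voom (0.0450), and without IL-33 library 2 (0.0139) or 4 (0.0412). Of 10 red blood cell and platelet genes, Pf4 rose by 0.72 and Ppbp fell by 1.38, and camera did not call the list (adjusted p = 0.786). Hbb-bs, with 73.0% of windows shared, had -0.40 and was not called, but was called at -0.51 with the replicate block. After the length correction Pf4 was at -0.08 and not called and Hbb-bs at -1.15 and called, with 2 genes of the list higher and 5 lower. Fat, thymus and mesothelium genes held 1 rise and 4 falls of 9, with Upk3b at -1.29 (camera adjusted p = 0.470).

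**Figure D4:**
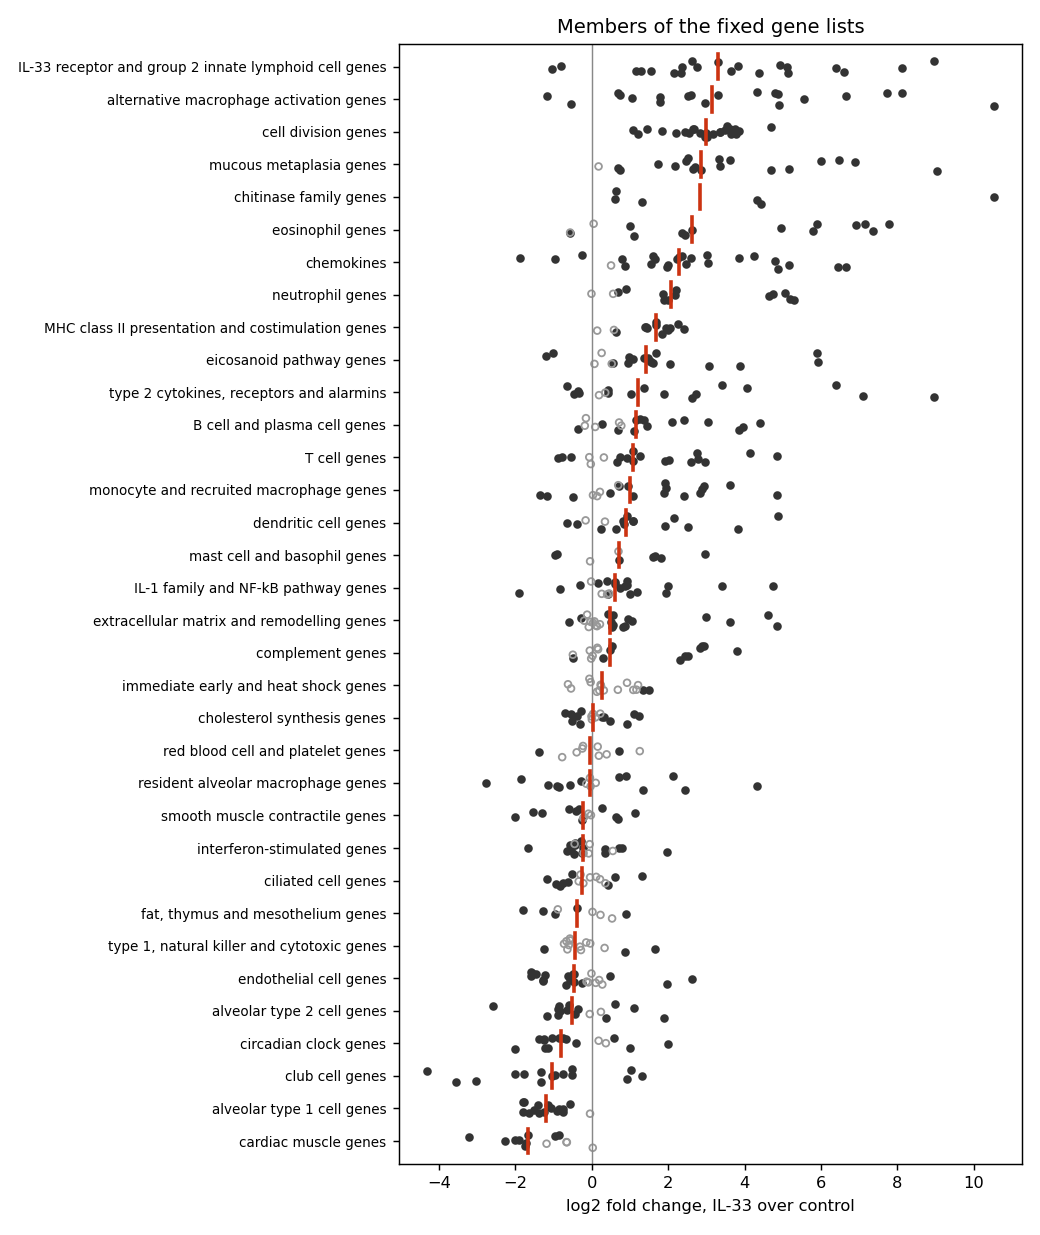
Log2 fold change (IL-33 over control) of each tested member of the 34 tested lists, in order of list median. Filled points passed an adjusted p of 0.05, open points did not, and bars mark medians, from 3.30 for the IL-33 receptor and group 2 innate lymphoid cell genes to -1.67 for cardiac muscle genes.

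Of the 34 lists, 22 passed camera at its preset correlation, 18 higher and 4 lower. With an estimated correlation 7 held, the IL-33 receptor, eosinophil, alternative macrophage activation, complement, cell division, eicosanoid and chitinase lists. The lists share members: 621 entries are 594 different genes. Xist, expressed from an inactive X chromosome, had 3932 to 9149 reads in every library, while the Y-linked Ddx3y, Eif2s3y and Uty had 0 reads in all and Kdm5d 2.

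The share of alignment records counted as multiply aligned was 15.6% ± 0.502 (SD, n = 5) in controls and 21.7% ± 1.21 (SD, n = 5) in IL-33 libraries, higher in all 5 than in any control (exact permutation test, two-sided, p = 0.00794, the smallest this design gives, and 0.0132 adjusted over 5 measures). Reads in no gene made up 10.8% ± 0.280 and 12.4% ± 0.889 (exact permutation p = 0.00794, adjusted 0.0132), and the 50 most abundant genes took 12.7% ± 0.378 and 14% ± 0.261 of counted reads (exact permutation p = 0.00794, adjusted 0.0132). Ambiguous reads, 0.926% and 0.906%, and counted totals gave exact permutation p-values of 0.230 and 0.944, adjusted 0.288 and 0.944.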

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

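The tests of library size, of 1 dilution factor (both lists), of the length slope within cell type lists and of ribosomal protein genes were chosen after the result was seen. Of 100 splits of the 10 libraries into 5 and 5, only 1, the real one, gave as many called genes, with 10975 against at most 0 in the others. The other splits mix control and IL-33 libraries within a group, so the difference between these adds to the spread within groups. Few or no calls were therefore likely there from the start. The splits cannot decide whether chance assignment explains the count, nor separate IL-33 from a batch aligned with group.

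The multiply aligned share was 21.7% in IL-33 libraries against 15% to 16.2% in single controls, a signal outside the gene counts. Totals of counted reads argue against library size, since 4 of the 5 IL-33 totals lay within the control range. Per 100 reads assigned to genes, multiply aligned records rose from 21.6 in controls to 33.6 in IL-33 libraries. Reads of the many gene copies that share sequence, such as Rpl23a, mt-Nd4 and Chil3, predicted 18.8% of that rise with 75-base windows. With 100-base and 50-base windows they predicted 13% and 25.9%, a range on both sides of the 20% bound set beforehand. The prediction counts reads, while the observed share counts alignment records, where a read may count several times. The prediction was also scaled from reads assigned to genes, so copies with nearly all windows shared may be missed. Both limits could make these percentages too low, so the bound cannot be judged. Shared reads therefore may account for a part and cannot be told apart from other sources, because the read length and the identity of the multiply aligned reads are not given in the sources used here. A change of RNA composition with IL-33 stays open and untested.

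Shorter transcripts were higher in IL-33 lungs, with a rho with length of -0.344 to -0.205 in IL-33 libraries and 0.214 to 0.343 in controls, for levels centred on the mean of all 10 libraries, which sets opposite signs. Within 101 genes of the 6 structural cell lists the slope was -0.31 per doubling of length (95% bootstrap interval -0.48 to -0.15). The bootstrap drew genes, not mice, and took them as independent, so the interval holds no spread between mice. Over all tested genes the slope was -0.31, a value that 1 trend acting on every gene would need. Such a trend might come from RNA integrity, fragment size or library batch, none of which is given per library in the sources used here and all of which the design could confound with IL-33. It falls short for ribosomal protein genes. Their median lay 1.26 above that of 1585 other genes within their range of length (0 of 10000 random lists reached it). For the 89 genes of the set seen first, which include S6 kinase genes, the difference was 1.08. Lengths were not matched gene by gene, so longer genes may add to this difference. Random lists ignore correlation between genes, and camera with an estimated correlation gave an adjusted p of 0.783 for Rpl and for Rps symbols. After the length and GC correction the median was 1.05, with 73 of 78 genes higher and 1 lower. Higher ribosomal protein RNA with IL-33 stays open as a hypothesis, limited by 27.5% of their windows, at the median, being shared with other genes.

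Alveolar type 1 and endothelial genes were lower in IL-33 lungs. Dilution of all parenchymal RNA by 1 factor is argued against for type 1 genes, whose mean log2 level minus that of type 2 genes shifted by -0.85 between groups (two-sided exact permutation p = 0.00794, the smallest this design gives). For endothelial genes it cannot be told apart from other sources, since their level minus that of type 2 genes shifted by -0.027 (exact permutation p = 0.746) while called members moved both ways, 14 lower and 3 higher. The type 2 list includes Il33, which rose by 1.88, so both shifts are lower than they would be without it. Shifts without Il33, or with the length trend removed, were not computed. The length and GC trend is argued against as well, because each list kept most of its fall. The type 1 median was -1.20 before and -1.18 after correction, and the endothelial median -0.48 and -0.43. The joint median of both lists was -0.97 after correction and -0.77 before, though neither list's own median fell further. A loss of these cells and lower expression per cell could both give this and were not separated, nor was an effect of IL-33 on either tested.

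Reads in no gene made up 12.4% in IL-33 libraries, above the 10.4% to 11.1% of controls. Of 213 groups of 5 values, 16 held a library far from the other 4 (gap over range above 0.71), where chance gives about 1 in 20. Control 2 and IL-33 library 2 each held 5 of these. Control 2 was high for Retnla (158 CPM, others 38.2 to 68.7), Fxyd4 (0.767, others 0 to 0.142), Chil3 (311, others 129 to 181), Clca1 (82.9, others 0.965 to 14) and Ccl8 (3.51, others 1.24 to 1.70 CPM). IL-33 library 2 was high for Spp1 (896 CPM, others 382 to 511), Mzb1 (92.2, others 21.6 to 38.2, uncertain with 75.7% of windows shared) and Cfi (16.9, others 12.8 to 13.5), and low for Il12rb2 (1.497, others 1.94 to 2.08) and Chia1 (1422, others 1973 to 2063 CPM). Scgb1a1 stood at 10698 CPM in IL-33 library 5 (others 12126 to 12636), and IL-33 library 1 was high for Selp (18.4, others 10.9 to 12.8) and Nfkbia (468, others 244 to 269 CPM). Control 1 was high for H2-Oa (4.39, others 1.64 to 2.37) and Ppbp (9.84, others 3.51 to 4.51), and control 3 for Cd80 (1.58, others 0.877 to 0.991 CPM). Without the library concerned, Clca1 moved from 6.46 to 8.38 and Fxyd4 from 7.43 to 8.75 (log2).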

How the results depend on the processing

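The length and GC correction and the leave-one-out of library measures were chosen after the results were seen. Calls ranged from 10517 to 12120 genes over the alternatives at an adjusted p of 0.05 against no change, and 9316 passed 0.01. A test against a 1.5-fold change called 4741 genes, 2813 higher and 1928 lower, since it asks for more. Without a low-count filter 3422 genes rose at least 2-fold, over more genes tested, and the alveolar type 2 and clock lists passed camera (adjusted p 0.0106 and 0.0178). With the length and GC correction the B cell list missed the threshold (0.0571), the type 2 list passed (0.010), and Mylk, Pf4 and Nfkbia turned sign without a call (0.070, -0.078 and -0.016), as did the resident macrophage list (0.784). With an estimated correlation camera's adjusted p was 0.0858 for the type 2 cytokine, dendritic cell, alveolar type 1, chemokine and MHC class II lists, 0.0767 for monocytes, 0.211 for neutrophils, 0.330 for T cells and matrix, 0.520 for B cells, 0.172 for mucous, 0.139 for club, 0.234 for endothelial, 0.328 for IL-1 family and 0.683 for cardiac genes. Fry, which does not compare a list with other genes, added mast cells (0.000213), resident macrophages (0.0179), type 2 cells (0.000484), interferon-stimulated genes (0.0432), clock (0.00289) and fat, thymus and mesothelium (0.0322). Leaving out 1 library at a time gave adjusted p of 0.00743 to 0.0763 for B cells (lost without control 2 or IL-33 library 5), 0.00155 to 0.0712 for cardiac genes (lost without control 2, control 5 or IL-33 library 5), 0.0284 to 0.0903 for type 2 cells (gained without control 5 or IL-33 library 4) and 0.0399 to 0.147 for clock genes (gained without control 1 or IL-33 library 4). Lists never called in these fits turned direction in some, with ranges of 0.420 to 0.954 for immediate early genes (without IL-33 library 2) and 0.657 to 0.983 for red cell genes (without control 3 or IL-33 library 2 or 4). The uncalled difference in counted totals ranged from -0.767 to 0.633 megareads and turned sign without control 1 or 4 or IL-33 library 2 or 3. The difference in ambiguous reads ranged from -0.0304 to -0.00954 percentage points, with an exact permutation p of 0.0476 without IL-33 library 5. With the replicate number as a block 11122 genes passed and the clock list gained its call (0.0213), as did Nfkbia, Jun and Hbb-bs among the named genes. The numbers do not pair the libraries: deviations of same-numbered libraries correlated at 0.24, 0.22, 0.06, -0.06 and 0.15, and in 0 of 5 numbers did each library correlate best with its own. Of 2160 values of named genes under alternatives, 2142 kept direction and side of the threshold, and 9 genes held the rest. With 200 of 15037 genes changed, simulated 1.5-fold changes were recovered in 53.7% of cases. Far more genes passed in the data, where the adjusted cutoff is less strict, so this share does not carry over. Whether depth or the number of libraries limits recovery was not tested. Unless a construction is named, the cause was not tested.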

Other observations

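The scan of gene families and the test of collection time were chosen after the result was seen. Among 260 symbol families of at least 8 tested genes, 25 passed camera (Benjamini-Hochberg adjusted over the families) and 0 with an estimated correlation, where all values are adjusted p of 0.324 or more. All 9 Ccr chemokine receptor genes rose, with a median log2 fold change of 2.20 (camera adjusted p = 4.62e-08; adjusted p = 0.324 with an estimated correlation). All 9 Serpina genes, which encode protease inhibitors, rose with a median of 2.07, and 2.01 after the length correction (camera adjusted p = 9.8e-06, adjusted p = 0.783 with an estimated correlation). So did all 10 Psmb genes of the proteasome, with a median of 0.95, and 0.64 after that correction (camera adjusted p = 0.000273, adjusted p = 0.783 with an estimated correlation). Of 48 Mrpl genes of the mitochondrial ribosome, 43 rose, with a median of 0.73, and 0.47 after the length correction (2.67e-06; adjusted p = 0.783 with an estimated correlation).

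All 11 Pcdhga protocadherin genes fell, with a median of -1.78 (camera adjusted p = 0.00384; adjusted p = 0.783 with an estimated correlation). They share constant exons, so their separate counts are uncertain. Of 20 Pcdhb genes, which do not share those exons, 18 fell, with a median of -1.05 (0.0112; adjusted p = 0.783 with an estimated correlation). Of 343 Zfp zinc finger genes 200 fell and 29 rose, with a median of -0.38 (0.000199; adjusted p = 0.783 with an estimated correlation).

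Clock genes moved as a hypothesis of collection at another time of day would need in part: Arntl, Clock, Npas2, Cry1 and Nfil3, which peak in antiphase to the others, had a median of 0.37 against -1.13, a difference of 1.502. That 0.37 is the value of Npas2, which did not pass, nor did Cry1 (0.18), and Clock fell by 0.42, while Arntl and Nfil3 rose by 0.59 and 2.003. Against it, Dbp and Tef fell by 1.13 and 1.24 while Hlf, which peaks with them, rose by 1.01, so collection time cannot be told apart from an effect of IL-33 on these genes, with no collection time given in the sources used here. The length and GC trend is argued against, since 11 of 14 called clock genes kept their call and direction after the correction.

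Zbtb16 fell from 185 ± 163 to 29.7 ± 18.8 CPM (SD, n = 5; log2 -2.64), with overlap between the groups, and Per1 by 1.25, both glucocorticoid-induced genes, chosen after their values were seen. A weaker glucocorticoid response may be a candidate explanation, and a separate list of 16 responsive genes had a median of -0.64, with 9 lower and 3 higher. Camera did not call that list (p = 0.474; p = 0.699 with an estimated correlation). Sgk1, Klf9 and Pdk4 fell by 0.81, 0.87 and 1.55. The 3 rises were Gadd45g, by 1.20, and the metallothionein genes Mt1 and Mt2, which also respond to metals and inflammation, by 2.65 and 3.11. Fkbp5 (0.57) and Tsc22d3 (-0.52) did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0820 and 0.0532), and the question stays open.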
